A study of Mus musculus with 29 samples.

How the data were processed

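RNA of 29 mouse gastric biopsies was compared on 2-colour cDNA arrays with a pool of age-matched control samples. The deposited values are 1 log2 ratio per probe and array. The log2 scale was read from the range of the deposited values, -12.96 to 8.69: as natural logs 2 of them, and as log10 2534, would lie beyond the widest ratio of a 16-bit scanner, so that base 2 is likely but not stated, and the labels give Cy3 for the pool and Cy5 for the biopsy on every array. The method of normalization, the direction of the ratio and any filter the authors applied are not given in the sources used here. The medians of the arrays as deposited lay between -0.54 (series D replicate 7) and 0.12 (series C replicate 4), so that not all arrays were centred on these probes. By array, with replicates in the order of their numbers, the medians were -0.09, -0.13, -0.13, 0.0020, 0.01 and -0.04 in series A, and -0.01, -0.12, -0.09, -0.01, -0.01, 0.06, -0.42 and -0.32 in series B. They were 0.0070, -0.03, 0.02, 0.12, 0.0010, -0.37 and -0.15 in series C, and -0.10, -0.02, 0.06, -0.06, -0.05, -0.19, -0.54 and -0.45 in series D. Of 42624 probes, 1 had no value and 23201 had a value on every array. The share of missing values was 0.57% to 10.54% per array.

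Probes were named from the platform annotation: 21701 had 1 gene symbol, 1124 had several and 19799 had none. Of the first, 21650 were found by gene number in the GRCm38 gene table, and 0 symbols had to be updated. Probes with no symbol or several entered only the fit on single probes. Each array's median was set to 0, and probes of 1 symbol were averaged, which gave 10843 genes, 5674 of them with more than 1 probe. Genes with values on at least 4 arrays of each group were tested, 10659 in all.

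The labels' letter was the group and their number the replicate. In limma 3.58.1 (R 4.3.3) 1 model with 4 group means was fitted to all 29 arrays, with 25 residual degrees of freedom where no value was missing and 4.51 prior degrees of freedom. The contrasts were the mean of the 4 groups against 0, each group against 0, the F test over the groups and the 6 pairs. The pool is 1 control sample, so a test against 0 leaves out the spread between control samples, and because no dyes were swapped a dye effect does not cancel against the pool. P-values were adjusted by the method of Benjamini and Hochberg over genes, with a threshold of 0.05, and tests were two-sided apart from F.

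The genes named were fixed by rule before the data were examined. Against the pool these were the 10 highest and 10 lowest past the threshold with 1 sign on at least 80% of the arrays. For each series against the pool they were the 3 highest and 3 lowest, for F the 15 smallest p, and for each pair the 4 largest differences in each direction. Of a list up to 4 members with the smallest p were named, and where no gene passed the 3 with the smallest p. B2m in series D, the values of Jchain and Igha in series A, and the acinar genes that did not fall, were given outside that rule, after their values were seen.

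The 30 gene lists, fixed before the data were examined, covered lymphoid and myeloid cells, gastric epithelium, neighbouring tissues and processes. Of these, 28 had at least 5 measured genes and were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, and again with a correlation estimated from residuals. The immunoglobulin list (Igha, Ighm and Ighv1-47) and the T cell list had fewer. The list of oxidative phosphorylation includes assembly factors. The chief cell list holds Amy1 and Rnase1, which the pancreas expresses too. The chemokine list shares 2 genes with the lymphoid follicle list and 1 with the interferon list. Relations between the means of lists were tested with 100000 permutations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1 for ranks).

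The fits were tested on simulated data for 10659 genes. For series A against series D, 33.2% of genes changed by 1 on the log2 scale were recovered and 85.6% of those changed by 2, with 4% false calls. For series C against series D a shift of 0.5 was found in 50 of 50 simulated lists of 20 genes, and 4 of 950 unshifted lists were called. The simulated genes varied independently, and each gene had the same spread on every array. Unequal spread between arrays was thus not tested.

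Image numbers in the labels fall into 3 runs: image run 1 with 24 arrays, image run 2 with 1 (series B replicate 2) and image run 3 with 4 (series B replicates 7 and 8, series D replicates 7 and 8). Within image run 1 the numbers of series A and B all lie below those of series C and D. Image order and series are thus not separated there. Arrays of image run 3 correlated with each other at r = 0.34 to 0.48 over probes, with a median of 0.447. The median was 0.144 for pairs of image run 3 with another run and 0.113 for pairs within image run 1. Over all runs it was 0.183 for pairs of 1 series and 0.123 for pairs of different series. Alternatives were the values with no centring, quantile normalization, scaling of all arrays to 1 spread, stricter and looser filters on missing values, single probes, only the arrays compared, array weights, a robust prior, blocks for replicate number and image run, image run 1 alone and each array left out. Leaving out the 5 arrays of widest spread (series A replicate 6, series B replicate 7, and series D replicates 3, 7 and 8), testing the lists within image run 1, and image run 3 alone, were added after seeing the data.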

Results

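The series asked about the role of antigens in the development of lymphoma of the mucosa-associated lymphoid tissue, and it measured RNA of mouse gastric biopsies on 29 arrays of 2 colours. On every array the biopsy carried the dye Cy5 and a pool of age-matched control samples carried Cy3, and the labels name Helicobacter pylori as the pathogen. The biopsies fell into 4 groups by the letter of their names, called series A (n = 6), series B (n = 8), series C (n = 7) and series D (n = 8) here. The labels do not say what the letters stand for, nor whether the biopsies of a letter came from separate animals, so that p-values measure the spread between these samples, which may be technical. Each array gave log2 ratios for 38131 to 42380 of 42624 probes. The spread of the ratios differed between arrays, with a median absolute deviation, scaled to the SD of normal values, from 0.33 (series B replicate 4) to 1.46 (series D replicate 3). The number of arrays limits the precision of the values given here.

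Signs follow the dyes in the labels: a positive log2 ratio is read as higher in the biopsy than in the pool. That direction is likely, as the pool is the first channel of every label and a reference is by custom the divisor, but the sources used here do not state it. If the ratio ran the other way, every higher value given here would be lower, so that 835 and 1511 would change places, and each difference between series would change its sign. The log base is likely 2, from the range of the values. No pair of arrays correlated below r = -0.19 over all probes.

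Against the pool, the mean of the 4 series held more RNA of Jchain, Igha and antigen presentation genes and less RNA of pancreatic digestive enzymes. Series A did not share the rises, with means of -0.53 for Jchain, -0.05 for Igha, 0.006 for B2m and -0.23 for H2-Ab1. In series C B2m was at 0.45 and H2-Ab1 at 0.17. The lists of MHC class I and II genes passed against the pool in series B and D, and not in series A and C. Jchain, the joining chain of secreted IgA and IgM, rose by a log2 ratio of 2.14 ± 0.18 (SE, 4.41-fold, adjusted p = 2.68e-09) and was above 0 on 24 of 29 arrays. Igha, the heavy chain of IgA, rose by 1.22 ± 0.13 (adjusted p = 2.64e-07, 25 of 29 arrays), while the other measured immunoglobulin genes, Ighm (0.15, adjusted p = 0.336) and Ighv1-47 (-0.13, adjusted p = 0.495), did not pass. Of the T cell genes Il7r (0.27), Cd3g (0.17), Il2rb (-0.20) and Cd8a (0.14) 0 passed (adjusted p from 0.0846 to 0.639). B2m, the light chain of MHC class I, rose by 0.90 ± 0.10, H2-Ab1, a chain of MHC class II, by 0.73 ± 0.13, and S100a9, a neutrophil calcium-binding protein, by 0.71 ± 0.12. Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, rose by 0.83 ± 0.08 and was above 0 on 28 of 29 arrays. Lamb2 (0.91), Prss40 (0.75), Dapl1 (0.74) and Mmd (0.72) completed the 10 highest. Lamb2 was 4.50 and 4.70 on series C replicates 3 and 7 and at most 1.65 on the other arrays. Mmd was measured on 20 arrays and was -1.59 on series D replicate 5.

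The 10 lowest were led by Sycn, a zymogen granule protein, at -3.03 ± 0.34 (SE, 8.16-fold lower, adjusted p = 5.42e-07, below 0 on 26 of 29 arrays). Cela3b, an elastase, followed at -2.94, the amylase Amy1 at -2.70, the trypsins Try4 at -2.65 and Try5 at -2.55, Cpb1 at -2.35, Ctrb1 at -2.34, 2210010C04Rik at -2.16, Ttc39a at -2.03 and Cpa1 at -2.01. Amy1 was -10.28 on series D replicate 2 and 0.26 on series C replicate 7, where Try4 was -0.44 and Try5 0.20. Probes of trypsin, amylase and H2 genes may bind transcripts of their close relatives.

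Of 10659 genes tested with limma, 2346 passed an adjusted p of 0.05, of which 835 were higher and 1511 lower. With no centring of the arrays 13% of the calls were higher, and with quantile normalization 10.4% of 4086, against 35.6% here. The median of all genes lay at -0.06 here and at -0.16 under both of those settings. Within image run 1, the 24 arrays whose image numbers lie close together, 1224 genes passed, and 2772 with the image run as a block. Without the 5 arrays of widest spread 1530 passed.

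**Figure D1:**
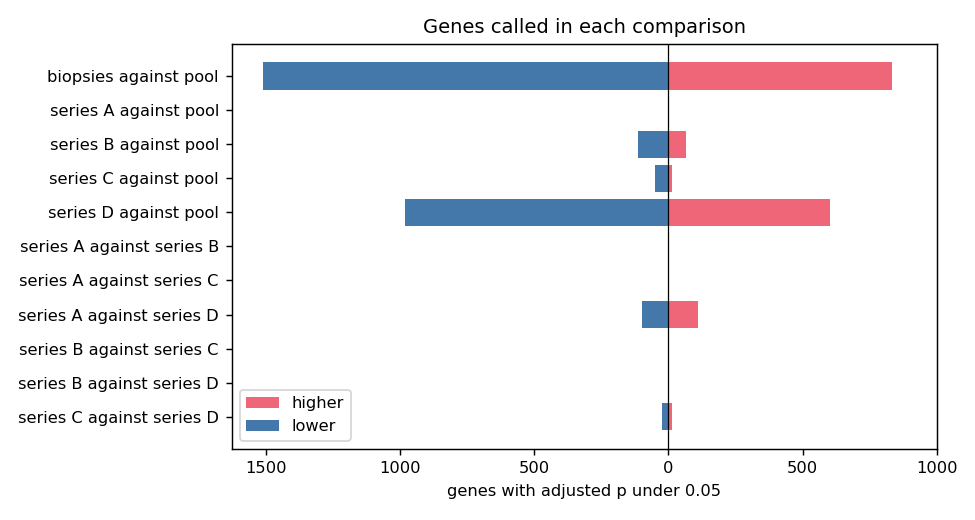
Number of genes with an adjusted p under 0.05 (horizontal axis) in each comparison with a direction, as bars to the right for genes that were higher and to the left for genes that were lower in the group named first. The biopsies against the pool gave 835 higher and 1511 lower genes, and series A against the pool gave 0.

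Gene lists fixed before the data were examined described these changes by cell type and process. Of 28 lists tested with camera, 11 passed against the pool, and 3 of these also passed with an estimated correlation. Among the 22 measured pancreatic acinar genes, 18 fell and 0 rose (18 adjusted over the list alone), with a median log2 ratio of -1.62 (adjusted p = 3.06e-29, and adjusted p = 0.00102 with an estimated correlation). Amy2a5 (0.04), Clps (0.0090), Cuzd1 (0.13) and Prss2 (0.27) did not pass. The MHC class II list rose, with 6 of 9 genes higher (6 adjusted over the list alone), a median of 0.30 and adjusted p = 6.9e-07 (adjusted p = 0.00161 with an estimated correlation). H2-Eb1 (0.54 ± 0.08) and H2-Aa (0.84 ± 0.17) were among them. The neutrophil list rose, with 5 of 10 genes higher and 1 lower (5 and 1 adjusted over the list alone), a median of 0.14 and adjusted p = 0.0108 (adjusted p = 0.0199 with an estimated correlation). It held S100a9, S100a8 (0.75 ± 0.16) and Mpo (0.55 ± 0.11).

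The remaining lists that passed against the pool did so with the preset correlation alone. In the MHC class I list 5 of 11 genes were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.23 and adjusted p = 9.8e-05 (adjusted p = 0.0973 with an estimated correlation). H2-D1 rose by 0.71, while H2-T10 fell by 0.54. In the B cell list 3 of 11 genes were higher (4 adjusted over the list alone): Ly86 (0.38), the surface protein Ms4a1 (0.43) and the complement receptor Cr2 (0.42). Its median was 0.20 and its adjusted p 0.0107 (adjusted p = 0.0801 with an estimated correlation). In the interferon response list 6 of 16 genes were higher (6 adjusted over the list alone), among them Bst2 (0.34) and Ifit1 (0.55), with adjusted p = 0.00263 (adjusted p = 0.0801 with an estimated correlation). In the macrophage and dendritic cell list 5 of 21 were higher (6 adjusted over the list alone), including Aif1 (0.41) and Coro1a (0.45), with adjusted p = 0.023 (adjusted p = 0.294 with an estimated correlation). In the chemokine and cytokine list 7 of 36 were higher and 2 lower (7 and 2 adjusted over the list alone), including Ccl4 (0.53) and Ccl6 (-0.36), with adjusted p = 0.0394 (adjusted p = 0.304 with an estimated correlation). The chemokine list had a median of 0.02, which was -0.08 with no centring and -0.03 with quantile normalization, and the macrophage median of 0.12 was -0.0060 with quantile normalization.

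Among 66 cytosolic ribosomal protein genes 40 were higher and 0 lower (48 adjusted over the list alone), led by Rpl39 (0.65) and Rps29 (0.58), with a median of 0.30 and adjusted p = 3.58e-25 (adjusted p = 0.142 with an estimated correlation). Among 92 genes of oxidative phosphorylation 23 were higher and 1 lower (24 and 1 adjusted over the list alone), including Cox6c (0.46), with a median of 0.15 and adjusted p = 4.31e-09 (adjusted p = 0.304 with an estimated correlation). In the intestinal metaplasia list 7 of 18 genes were lower (7 lower and 1 higher adjusted over the list alone), with a median of -0.30 and adjusted p = 0.0394 (adjusted p = 0.338 with an estimated correlation). The lowest were Reg3b (-1.97 ± 0.24) and Reg3a (-1.45 ± 0.26), secreted lectins that the pancreas also makes, and Pigr (-0.93 ± 0.16), the receptor that carries IgA across epithelium. All 11 lists passed within image run 1. With the image run as a block the chemokine (adjusted p = 0.0596) and metaplasia (adjusted p = 0.0652) lists did not.

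Lists that did not pass included those of gastric epithelium. The median was -0.28 for chief cell genes (adjusted p = 0.0612, and 0.00701 within image run 1), 0.12 for surface and neck mucous cell genes (adjusted p = 0.0693), -0.26 for enteroendocrine genes (adjusted p = 0.228) and -0.02 for parietal cell genes (adjusted p = 0.491). The chief cell genes that fell were Amy1, Rnase1 (-1.76 ± 0.20), a ribonuclease the pancreas also makes, and Pgc (-0.52 ± 0.18), a pepsinogen. Tff1 (0.59 ± 0.13), a trefoil peptide of mucous cells, rose. The lymphoid follicle (median 0.17, adjusted p = 0.0671) and fibroblast and matrix (0.05, adjusted p = 0.188) lists did not pass. Adjusted p lay between 0.491 and 0.914 for the lists of plasma cells, mast cells, general epithelium, proliferation, smooth muscle, endothelium, squamous forestomach, adipocytes, skeletal muscle, red cells and endoplasmic reticulum stress. Their medians were -0.0020, 0.06, -0.0010, -0.04, 0.06, -0.10, -0.03, -0.11, -0.07, -0.0090 and 0.02. The test had another sign than the median or mean in the plasma cell, mast cell, parietal cell, general epithelium, proliferation, smooth muscle, fibroblast, forestomach, red cell and endoplasmic reticulum lists.

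**Figure D2:**
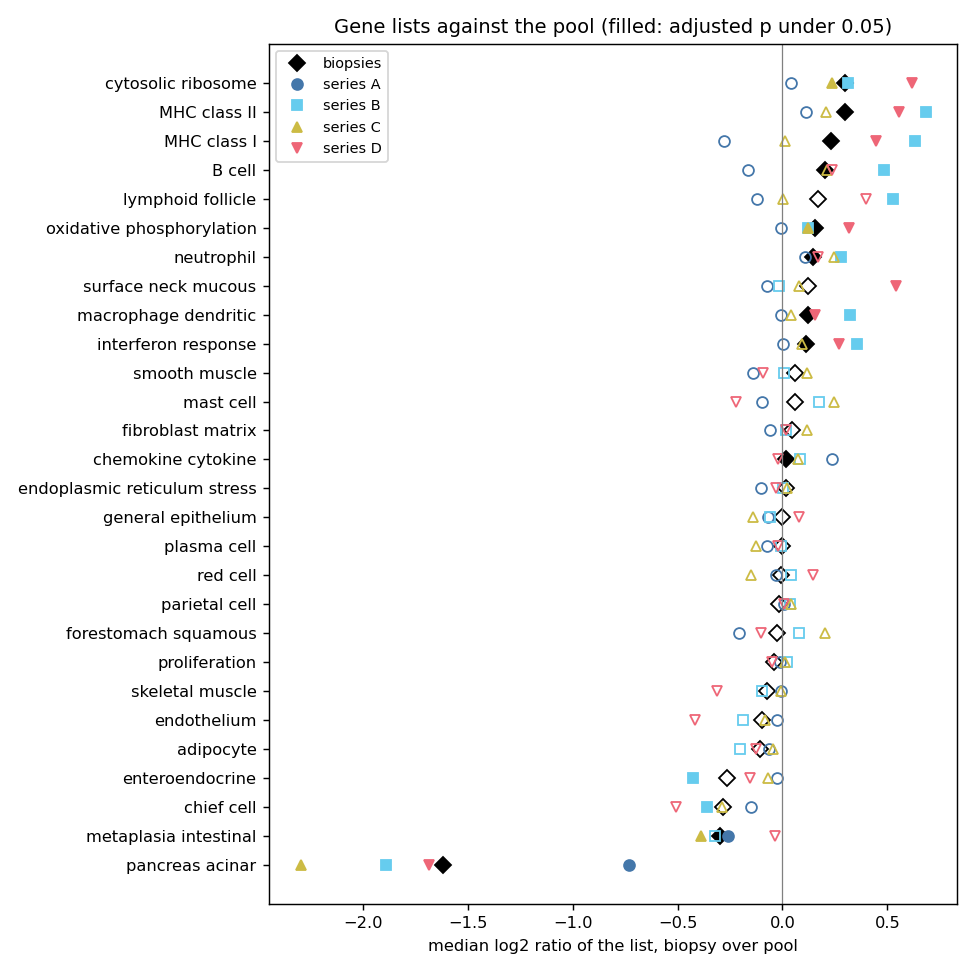
Median log2 ratio of biopsy over pool (horizontal axis) of each tested gene list (vertical axis), for the mean of the 4 groups and for each series, with filled symbols where the list passed an adjusted p of 0.05 with the preset correlation. The pancreatic acinar list had medians from -0.73 in series A to -2.30 in series C.

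Each series was then set against the pool. In series B the 3 highest genes were Jchain at 3.31 ± 0.73, Igha at 2.19 ± 0.66 and the MHC class II chain H2-Aa at 1.61 ± 0.78 (SD, n = 8), each above 0 on 8 of 8 arrays. The 3 lowest were Cela3b at -3.57 ± 1.68, Try4 at -3.19 ± 1.68 and Sycn at -3.07 ± 1.32 (SD, n = 8). In limma 182 genes passed in series B, 67 higher and 115 lower, against 39 within image run 1, 124 with the image run as a block and 100 in a fit on series B alone, and against 1006 with quantile normalization, 594 with array weights and 494 with all arrays scaled to 1 spread. H2-Aa (1.27), Cela3b (-3.29), Try4 (-2.97) and Sycn (-2.48) did not pass within image run 1. Leaving out series B replicate 3, 6, 7 or 8 gave 116, 111, 118 or 94 genes.

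By gene list, series B was above the pool in MHC class II (median 0.69, adjusted p = 5.41e-11), MHC class I (0.63, adjusted p = 2.67e-10), lymphoid follicle (0.53, adjusted p = 0.00353), B cell (0.48, adjusted p = 2.35e-05), interferon response (0.35, adjusted p = 6.04e-06), macrophage and dendritic cell (0.32, adjusted p = 7.6e-05) and neutrophil genes (0.28, adjusted p = 0.000709). These 7 also passed with an estimated correlation and within image run 1. Of the MHC class II genes 3 of 9 passed over all genes and 7 adjusted over the list alone, of the MHC class I genes 4 and 7 of 11, and of the B cell genes 1 and 2 of 11. Enteroendocrine genes were lower in series B (median -0.42, adjusted p = 0.00189, and adjusted p = 0.00174 with an estimated correlation), with 1 of 11 genes past the threshold and 6 adjusted over the list alone. Gast, the hormone gastrin, fell by 1.62 ± 0.26 (SE). The acinar list was lower (median -1.89, adjusted p = 2.27e-22, and adjusted p = 0.00174 with an estimated correlation), as was the chief cell list (median -0.36, adjusted p = 0.0222, and adjusted p = 0.186 with an estimated correlation), in which Amy1 and Rnase1 passed. Ribosomal protein genes had a median of 0.31 (adjusted p = 3.39e-14, and adjusted p = 0.274 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.12 (adjusted p = 7.6e-05, and adjusted p = 0.512 with an estimated correlation), which was -0.07 within image run 1 (adjusted p = 0.649). On the 2 arrays of series B in image run 3 limma gave 0 genes (1629 at an unadjusted p under 0.05), Jchain was at 4.15, and the lists of B cell, MHC class I and II, acinar, oxidative phosphorylation (median 0.66) and ribosomal genes (0.98) passed, while the others named here did not (adjusted p from 0.0973 to 0.363).

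In series D the 3 highest genes were Jchain at 3.63 ± 0.98 (SD, n = 8), Man1b1 at 2.24 ± 2.40 (SD, n = 5) and H2-Aa, which rose 4.01-fold and was above 0 on 8 of 8 arrays. B2m was at 1.90 ± 0.49 (SD, n = 8). Man1b1 did not pass without series D replicate 2 (1.63, adjusted p = 0.074) or 7 (1.55, adjusted p = 0.0853). The 3 lowest were Amy1 (-3.14 ± 3.17, SD, n = 8), Sycn (-2.79 ± 1.96, SD, n = 8) and Ttc21a (-2.79 ± 1.24, SD, n = 4). In limma 1585 genes passed, 604 higher and 981 lower, against 875 within image run 1 and 1317 with the image run as a block. A fit on series D alone gave 255, without Man1b1 (adjusted p = 0.133) and Amy1 (adjusted p = 0.0767). Scaling all arrays to 1 spread gave 329, without Man1b1 (1.58, adjusted p = 0.18), Amy1 (-2.47, adjusted p = 0.074) and Sycn (-2.10, adjusted p = 0.152), and leaving out series D replicate 1 or 8 gave 1034 or 991.

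Series D was above the pool in MHC class II (median 0.55, adjusted p = 2.17e-05) and MHC class I genes (0.45, adjusted p = 2.52e-07), and both lists also passed with an estimated correlation. Of these, 4 of 9 and 3 of 11 genes passed over all genes, and 4 and 6 adjusted over the list alone. In the surface and neck mucous cell list 4 of 10 genes were higher (4 adjusted over the list alone): Ctse (0.79), Gkn2 (0.69), Tff1 (0.81) and Gkn1 (0.65). Its adjusted p was 0.00152 (adjusted p = 0.334 with an estimated correlation, and 0.121 within image run 1). Ribosomal protein genes had a median of 0.62, with 38 of 66 higher (54 adjusted over the list alone) and adjusted p = 4.32e-35 (adjusted p = 0.115 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.32, with 31 of 92 higher and 1 lower (35 and 2 adjusted over the list alone) and adjusted p = 1.9e-15 (adjusted p = 0.236 with an estimated correlation). The acinar list was lower (median -1.68, adjusted p = 6.21e-09, and adjusted p = 0.181 with an estimated correlation), with 16 of 22 genes lower and Cuzd1 (0.58) higher. The macrophage and dendritic cell (median 0.16, or -0.015 with no centring, adjusted p = 0.0247) and interferon response (adjusted p = 0.0302) lists passed, but not with an estimated correlation (adjusted p = 0.276 and 0.246) or within image run 1 (adjusted p = 0.0975 and 0.0937). On the 2 arrays of series D in image run 3 limma gave 0 genes (2327 at an unadjusted p under 0.05), with Jchain at 2.51, Amy1 at -0.73 and Sycn at -1.18. There the ribosomal (median 1.22), oxidative phosphorylation (0.76), surface mucous (1.12) and both MHC lists passed, but the acinar (-0.81, adjusted p = 0.632), macrophage (adjusted p = 0.124) and interferon lists (adjusted p = 0.361) did not.

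In series C, Jchain was the highest at 2.15 ± 1.33 (SD, n = 7) and was above 0 on 7 of 7 arrays, followed by 1700027I24Rik (1.76 ± 1.61, SD, n = 6) and Gm12258 (1.61 ± 1.67, SD, n = 5). Gm12258 was 3.96 on series C replicate 7 and 2.68 on series C replicate 4. 1700027I24Rik did not pass within image run 1 (1.76, adjusted p = 0.0627), and its call ended with any of 19 single arrays left out (1.24 to 1.84, adjusted p from 0.0502 to 0.161). That of Gm12258 ended with any of 5 (1.02 to 1.74, adjusted p from 0.0501 to 0.279). Sycn (-4.83 ± 2.52, SD, n = 7), Cela3b (-4.52 ± 2.50, SD, n = 6) and Try4 (-3.98 ± 1.64, SD, n = 7) were the lowest. Series C replicate 7 lay apart, with a mean of the acinar list of 0.03. The acinar list fell in series C (median -2.30, adjusted p = 5.17e-43, and adjusted p = 1.43e-05 with an estimated correlation), with 15 of 22 genes lower (18 adjusted over the list alone). The metaplasia (median -0.39, adjusted p = 0.0208), oxidative phosphorylation (0.12, adjusted p = 0.000453) and ribosomal (0.24, adjusted p = 4.99e-11) lists passed, but not with an estimated correlation (adjusted p = 0.642, 0.858 and 0.69), and the metaplasia list not with the image run as a block (adjusted p = 0.185). In limma 66 genes passed, 15 higher and 51 lower, 72 within image run 1, 160 with the image run as a block, 474 with quantile normalization, 216 with all arrays scaled to 1 spread and 135 with array weights. Series C lies in image run 1 alone, so that the run effect in the block was estimated from series B and D. In a fit on series C alone 0 passed, and leaving out series C replicate 2 or 7 gave 34 or 43.

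In series A, Jchain was -0.53 ± 0.84 and Igha -0.05 ± 0.46 (SD, n = 6). No gene of series A passed in limma, with 1016 genes at an unadjusted p under 0.05, and 0 passed within image run 1 or with the image run as a block. Tgfb1 (0.99), Kdm3a (-1.01) and Dnajc17 (-1.03) had the smallest p, all with adjusted p = 0.207. Tgfb1 was 0.03 on series A replicate 11. The probes of Kdm3a ranged from -3.06 to -0.10 and those of Dnajc17 from -2.12 to 0.07, and Dnajc17 passed without series A replicate 10 (-1.29, adjusted p = 0.0417). The acinar (median -0.73) and metaplasia (-0.26) lists passed in series A, each with adjusted p = 0.0123, but not with an estimated correlation (adjusted p = 0.969 for both) or with the image run as a block (adjusted p = 0.189 for both). Series A too lies in image run 1 alone, so that the run effect in the block was estimated from series B and D. The mean of the acinar list was -1.39, -1.22 and -1.76 on series A replicates 7, 8 and 10, and 0.11, -0.07 and 0.86 on replicates 6, 9 and 11. The acinar and metaplasia lists did not pass with quantile normalization (adjusted p = 0.373 and 0.0734) or with all arrays scaled to 1 spread (adjusted p = 0.0565 for both). With quantile normalization 600 genes passed in series A, with array weights 210 and with all arrays scaled to 1 spread 190, and under each of these Tgfb1, Kdm3a and Dnajc17 passed.

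**Figure D3:**
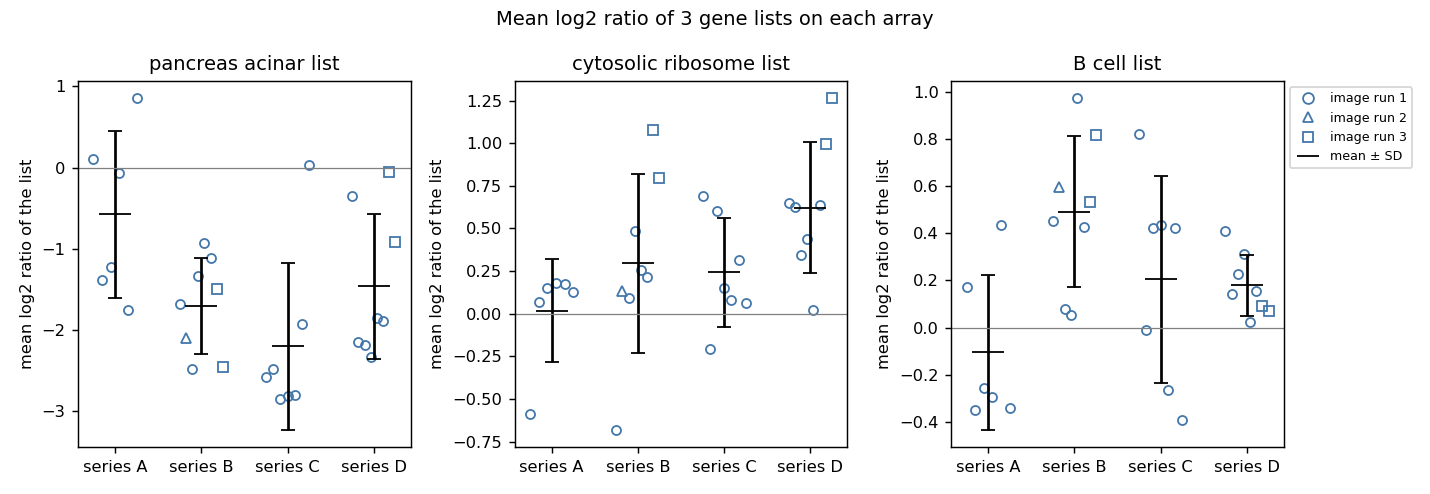
Mean log2 ratio of biopsy over pool of the pancreatic acinar, cytosolic ribosome and B cell lists (vertical axes) on each of the 29 arrays by series, with the symbol showing the image run and black bars the mean ± SD. The acinar list ranged from -2.85 to 0.03 in series C, and the ribosomal list reached 1.27 in series D.

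Each array set 1 biopsy against the same pool, through which the series can be compared with each other, and the moderated F test asked whether the 4 series differed. Jchain had the smallest p (adjusted p = 0.000171), and B2m, Nfkb2 and 1810021M19Rik followed (each adjusted p = 0.00365). Nfkb2, a subunit of the transcription factor NF-kappaB, had a mean of 1.19 ± 0.33 (SD, n = 8) in series D, against -0.33, -0.13 and -0.10 in series A, B and C. Series D also had the highest means of Ddx1 (1.37), Tmem123 (1.04), Adam9 (1.18), Rbm3 (1.32) and Cd164 (0.94). AW112010, Plac8 and Nt5e, an ectonucleotidase, had means of 1.97, 1.16 and 1.25 in series D and of 1.02, 0.89 and 0.66 in series B, and lay between -0.33 and 0.31 in series A and C. Series D had the lowest mean in 1810021M19Rik (-1.55), Ramp1 (-1.89) and Lrwd1 (-1.57). Igha completed the 15 genes. Single arrays lay apart in some of them, such as Adam9 at 2.95 on series D replicate 1, Nfkb2 (-1.16) and Cd164 (-1.11) on series A replicate 6, Plac8 at 0.74 on series A replicate 9, and 1810021M19Rik (1.36) and Lrwd1 (1.64) on series C replicate 2. In all 39 genes passed. Within image run 1 the count was 65, of which 31 were among the 39, and with the image run as a block 20, without Igha (adjusted p = 0.0598) and Lrwd1 (adjusted p = 0.057). With all arrays scaled to 1 spread Nfkb2, 1810021M19Rik and Cd164 passed and no other gene, with Jchain at adjusted p = 0.0933 and B2m at 0.251. Without the 5 arrays of widest spread 1810021M19Rik (adjusted p = 0.064), Nt5e (0.064), Ramp1 (0.126) and Lrwd1 (0.0986) did not pass. With the replicate number as a block Plac8 (adjusted p = 0.0635), Nt5e (0.0791), Adam9 (0.0638), Rbm3 (0.106), Cd164 (0.0638) and Lrwd1 (0.0901) did not pass. Leaving out series D replicate 5 gave 158 genes, series B replicate 7 gave 74 and series D replicate 4 gave 24.

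**Figure D4:**
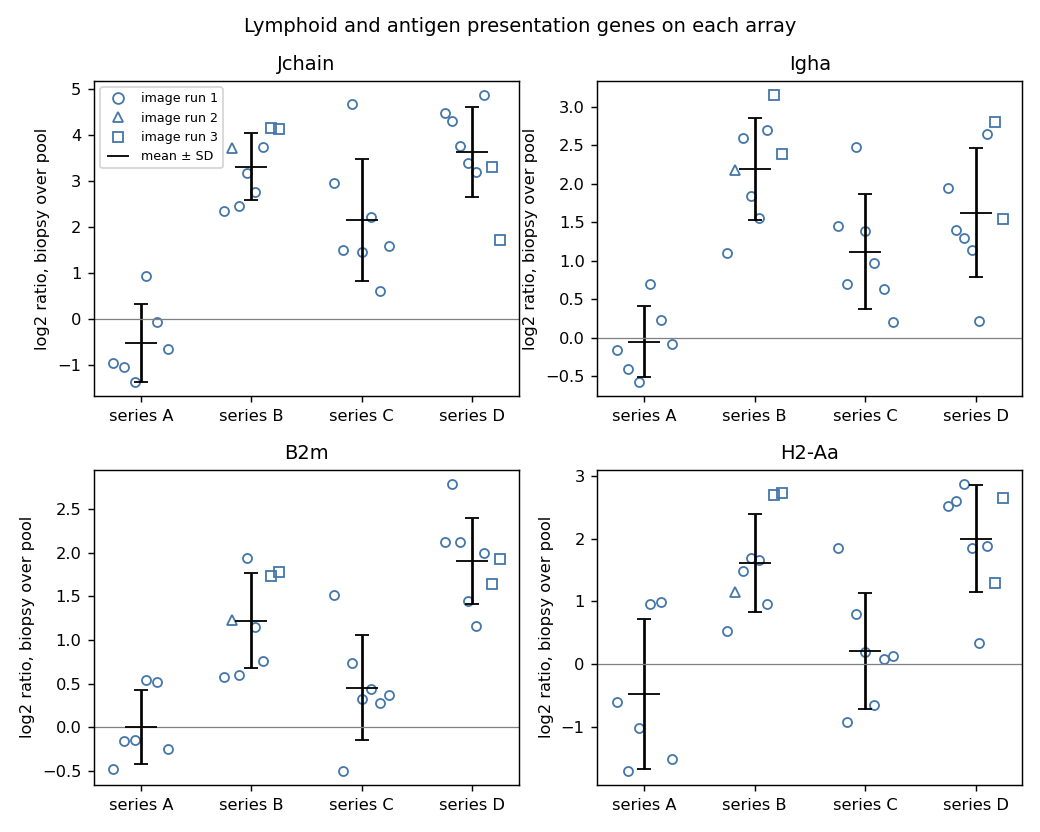
Log2 ratio of biopsy over pool (vertical axes) of Jchain, Igha, B2m and H2-Aa on each of the 29 arrays by series, with the symbol showing the image run and black bars the mean ± SD. Jchain lay between -1.37 and 0.94 in series A and between 2.34 and 4.16 in series B.

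Between series A and D, Jchain was lower in series A by a log2 difference of -4.16 ± 0.51 (SE, adjusted p = 4.73e-05), Ms4a6b by -2.49 ± 0.45, H2-Aa by -2.49 ± 0.48 and AW112010 by -2.30 ± 0.35. Higher in series A were Cldn13 (2.45 ± 0.60), Ttc21a (2.23 ± 0.58), Oplah (2.20 ± 0.53) and Dnph1 (2.17 ± 0.44). Cldn13 was 5.27 on series A replicate 10 and at most 1.17 on the other arrays of series A, and Ttc21a was measured on 4 arrays of series D. Cldn13 did not pass without series A replicate 6 (adjusted p = 0.0896) or series D replicate 1 (0.0754) or 2 (0.0578). The call of Ttc21a ended with any of 14 single arrays left out (2.10 to 2.27, adjusted p up to 0.112) and that of Oplah with any of 7 (1.76 to 2.27, up to 0.0883). With the image run as a block these 3 had differences of 2.45, 2.23 and 2.17 and did not pass (adjusted p = 0.0615, 0.072 and 0.0641), nor did Oplah within image run 1 (2.05, adjusted p = 0.0615). With all arrays scaled to 1 spread 41 genes passed, Dnph1 alone of those named, with Jchain at -3.25 (adjusted p = 0.0564), Ms4a6b at -2.42 (0.0519), H2-Aa at -1.86 (0.125) and AW112010 at -1.76 (0.0542). Without the 5 arrays of widest spread 33 passed, without H2-Aa (-2.30, adjusted p = 0.081), Dnph1 (1.92, 0.118), Cldn13 (2.65, 0.0962) and Oplah (1.47, 0.25). Ttc21a then had too few values in series D to be tested. In all 209 genes passed, 112 higher and 97 lower in series A, 239 within image run 1 and 58 with the image run as a block. A fit on these 2 series alone gave 62, without Cldn13 (adjusted p = 0.149), Ttc21a (0.0885) and Oplah (0.0769). Without centring 68.2% of the calls were higher, against 53.6% here, and the median difference of all genes moved from 0.09 to 0.19. Leaving out series A replicate 6 gave 29 genes, and replicates 7, 8, 10 and 11 gave 81, 134, 82 and 88. Leaving out series D replicate 1, 3 or 5 gave 115, 128 or 416.

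In the MHC class I list 3 of 11 genes were lower in series A than in series D (5 adjusted over the list alone), B2m by -1.90, H2-D1 by -1.80 and H2-K1 by -1.75, and the list passed (median -0.78, adjusted p = 1.7e-08, and adjusted p = 0.0339 with an estimated correlation). Ribosomal protein genes (median -0.63, adjusted p = 1e-22, 5 of 66 lower and 33 adjusted over the list alone) and oxidative phosphorylation genes (adjusted p = 1.2e-11) were lower in series A, and acinar genes were higher (adjusted p = 0.00814). With an estimated correlation these gave adjusted p = 0.352, 0.495 and 0.549. MHC class II (median -0.57, adjusted p = 0.00899), surface mucous (-0.51, adjusted p = 0.00814), metaplasia (-0.30, adjusted p = 0.0383) and macrophage genes (-0.28, adjusted p = 0.0404) were lower in series A. With an estimated correlation they gave adjusted p = 0.347, 0.518, 0.495 and 0.495, and within image run 1 adjusted p = 0.0531, 0.223, 0.574 and 0.193. With quantile normalization these 4 did not pass either (adjusted p = 0.144, 0.169, 0.0616 and 0.0616), nor with all arrays scaled to 1 spread (adjusted p = 0.47, 0.255, 0.0724 and 0.0921), where the acinar list had a median of 0.35 (adjusted p = 0.541).

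Series A and B differed in Jchain (-3.84 ± 0.51, SE, adjusted p = 0.000238) and Igha (-2.24 ± 0.37, adjusted p = 0.00638), both lower in series A, and in no other gene (657 at an unadjusted p under 0.05). The probes of Igha differed by -3.10 and -1.38. Igha did not pass within image run 1 and with the image run as a block (-2.01 and -2.02, adjusted p = 0.133 and 0.0722), and with all arrays scaled to 1 spread 0 genes passed, with Jchain at -4.12 and Igha at -2.29 (both adjusted p = 0.0806). By list, B cell genes were lower in series A than in series B (median -0.71, adjusted p = 2.65e-05, and adjusted p = 0.00133 with an estimated correlation), as were MHC class I genes (-0.98, adjusted p = 5.89e-14) and MHC class II genes (-0.58, adjusted p = 1.62e-06), which also passed with an estimated correlation. In these 3 lists 0 genes passed over all genes, and 1, 6 and 3 were lower adjusted over the list alone. Lymphoid follicle (-0.49), macrophage (-0.33), neutrophil (-0.25) and interferon genes (-0.24) were lower and enteroendocrine genes (0.42) higher in series A, and all 5 passed with an estimated correlation and within image run 1. Acinar genes were higher in series A (median 1.12, adjusted p = 1.78e-09, and adjusted p = 0.0705 with an estimated correlation). Ribosomal (median -0.29, adjusted p = 1.49e-09), oxidative phosphorylation (-0.14, adjusted p = 0.000187) and forestomach genes (-0.29, adjusted p = 0.00312) were lower in series A, but not with an estimated correlation (adjusted p from 0.311 to 0.534), within image run 1 (adjusted p = 0.17, 0.793 and 0.988) or with the image run as a block (adjusted p = 0.063, 0.593 and 0.363). Within image run 1 the medians of oxidative phosphorylation and forestomach genes turned to 0.04 and 0.10.

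Between series A and C, Jchain differed by -2.67 ± 0.52 (SE) and had the smallest p (adjusted p = 0.189), before Fgd6 (-2.05) and Pla2r1 (-0.81), both with adjusted p = 0.996. In limma 0 genes passed (399 at an unadjusted p under 0.05), as within image run 1, but with array weights 12 did, among them Jchain (-2.90, adjusted p = 0.00802). The acinar list was higher in series A (median 1.69, adjusted p = 1.5e-22, and adjusted p = 0.00823 with an estimated correlation), with 0 of 22 genes past the threshold over all genes and 13 adjusted over the list alone. The B cell (median -0.26, adjusted p = 0.0236), MHC class I (-0.35, adjusted p = 0.0118) and ribosomal lists (-0.21, adjusted p = 1.87e-07) were lower in series A, but not with an estimated correlation (adjusted p = 0.347, 0.585 and 0.813). Oxidative phosphorylation (-0.16, adjusted p = 0.000582), forestomach (-0.37, adjusted p = 0.00454), endoplasmic reticulum stress (-0.15, adjusted p = 0.0166) and fibroblast and matrix genes (-0.24, adjusted p = 0.0479) were lower too, with adjusted p from 0.585 to 0.931 with an estimated correlation. With the image run as a block the fibroblast and matrix list did not pass (adjusted p = 0.06). Without the 5 arrays of widest spread 3 lists were called, against 8 here.

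Between series C and D, AW112010 (-1.67 ± 0.34, SE), H2-K1 (-1.48 ± 0.34), B2m (-1.45 ± 0.27) and Adam9 (-1.43 ± 0.27) were lower in series C, and Lhb (2.49 ± 0.56), Krtap26-1 (2.08 ± 0.44), 4933432K03Rik (1.79 ± 0.37) and 1810021M19Rik (1.74 ± 0.30) higher. Lhb was 4.14 on series C replicate 2. Without that array 3 genes passed, and of those named, 1810021M19Rik alone did. The call of H2-K1 ended with any of 19 single arrays left out (-1.52 to -1.31, adjusted p up to 0.131), that of Lhb with any of 15 (1.95 to 2.58) and that of Krtap26-1 with any of 8 (1.90 to 2.06, both up to 0.0944). With the image run as a block 4933432K03Rik (1.72, adjusted p = 0.0541), AW112010 (-1.55, 0.0543) and H2-K1 (-1.33, 0.107) did not pass, and within image run 1 H2-K1 (-1.34, 0.0841) did not. With all arrays scaled to 1 spread 2 genes passed and none of those named, with B2m at -0.73 (adjusted p = 0.546), AW112010 at -1.02 (0.407) and H2-K1 at -1.01 (0.333). In all 36 genes passed, 13 higher and 23 lower in series C, 66 within image run 1 and 18 with the image run as a block. Without centring 18 passed, 11 of them higher, with quantile normalization 4, and in a fit on these 2 series alone 0. Of the named genes 1810021M19Rik alone passed with quantile normalization, with B2m at -1.23 (adjusted p = 0.0775) and H2-K1 at -1.32 (0.151). Without the 5 arrays of widest spread 4933432K03Rik (adjusted p = 0.0733), AW112010 (0.0539) and H2-K1 (0.123) did not pass. With the replicate number as a block none of the named genes passed (adjusted p from 0.0717 to 0.141). Leaving out series C replicate 4 or 7 gave 19 or 20 genes, series D replicate 1, 2, 3, 5 or 6 gave 16, 8, 15, 106 or 20, and series B replicate 1 or 7 gave 56 or 57. MHC class I genes (median -0.36, adjusted p = 5.79e-05) and ribosomal genes (-0.37, adjusted p = 9.93e-12) were lower in series C, but not with an estimated correlation (adjusted p = 0.323 and 0.578). MHC class II (median -0.42, adjusted p = 0.00945), surface mucous (-0.21, adjusted p = 0.0282), metaplasia (-0.41, adjusted p = 0.0279), acinar (-0.80, adjusted p = 0.000648) and oxidative phosphorylation genes (-0.24, adjusted p = 4.33e-06) were lower too, with adjusted p from 0.323 to 0.593 with an estimated correlation and adjusted p = 0.107, 0.527, 0.591, 0.378 and 0.0709 within image run 1. With all arrays scaled to 1 spread the acinar list alone of these 7 passed, with MHC class I at -0.21 and ribosomal genes at -0.09 (both adjusted p = 0.109). Without the 5 arrays of widest spread 3 lists were called, against 7 here.

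Series B and D differed in Vav3 (-1.47 ± 0.26, SE) and Nfkb2 (-1.31 ± 0.23), both lower in series B with adjusted p = 0.0209. With the replicate number as a block neither passed (adjusted p = 0.0641 and 0.139). The count of 2 was 53 within image run 1, 90 with array weights, 0 with all arrays scaled to 1 spread (Vav3 -1.38 and Nfkb2 -1.03, adjusted p = 0.0691 and 0.0722) and 5 with the image run as a block. In a fit on these 2 series alone 0 genes passed, with both at adjusted p = 0.293, and with quantile normalization Nfkb2 did not (-1.12, adjusted p = 0.0804). Within image run 3, with 2 arrays of each series, it was 0 in limma (470 genes at an unadjusted p under 0.05), with Vav3 at -0.57 and Nfkb2 at -0.37. Over all arrays it was 0 without series B replicate 1, 2, 5 or 6 or series D replicate 1 or 2, and 49, 4, 30, 14 and 5 without series B replicate 7 and series D replicates 3, 5, 6 and 7. Ribosomal (median -0.37, adjusted p = 1.07e-10), oxidative phosphorylation (-0.21, adjusted p = 1.25e-06) and surface mucous genes (-0.37, adjusted p = 0.0122) were lower in series B, but not with an estimated correlation (adjusted p = 0.715, 0.723 and 0.715), and the surface mucous list not within image run 1 (adjusted p = 0.0544). Within image run 3 these lists had medians of -0.18, -0.05 and -0.47 and did not pass (adjusted p = 0.0569, 0.94 and 0.374). The surface mucous list did not pass with quantile normalization (adjusted p = 0.0891) or with all arrays scaled to 1 spread (0.0534).

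Between series B and C, MHC class II (median 0.69, adjusted p = 1.08e-05) and MHC class I genes (0.62, adjusted p = 2.77e-06) were higher and enteroendocrine genes (-0.23, adjusted p = 0.0123) lower in series B, and the 3 lists also passed with an estimated correlation and within image run 1. In these, 0 genes passed over all genes, and 5, 3 and 1 adjusted over the list alone. Macrophage (0.31, adjusted p = 0.00214), interferon response (0.27, adjusted p = 0.00214), lymphoid follicle (0.32, adjusted p = 0.034) and acinar genes (0.56, adjusted p = 0.0123) were higher in series B, but not with an estimated correlation (adjusted p = 0.11, 0.0712, 0.0824 and 0.701), and the lymphoid follicle list not within image run 1 (adjusted p = 0.104), with quantile normalization (0.103) or with all arrays scaled to 1 spread (0.241). In limma 0 genes passed (626 at an unadjusted p under 0.05), as within image run 1. Lyzl1 (-2.41), Eif4h (0.96) and Nefh (-1.55) had the smallest p, each with adjusted p = 0.559, and Lyzl1 was 3.11 on series C replicate 4.

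Relations between lists were tested over the 29 arrays for 8 pairs of lists, by permutation. The means of the B cell and MHC class II lists varied together (Pearson r = 0.60, permutation p = 0.00067, adjusted p = 0.00268, Spearman rho = 0.49, permutation p = 0.00794). Without the 2 arrays farthest from the median r was 0.58, within image run 1 it was 0.62, and on deviations from the group means 0.51. Parietal cell genes and surface and neck mucous cell genes varied together (r = 0.72, permutation p = 2e-05, adjusted p = 0.00016, rho = 0.70, permutation p = 0.0001), with r = 0.69 without the 2 farthest arrays, 0.58 within image run 1 and 0.80 on deviations from the group means. The farthest arrays were chosen by the first list of a pair alone. Series A replicate 6 and series B replicate 1 were low in both lists, and series B replicate 7 and series D replicates 7 and 8 were high. The same arrays were low or high in the ribosomal and oxidative phosphorylation lists. A shift shared by many genes of an array was not tested as the cause. The 3 immunoglobulin genes and the B cell list had r = 0.50 (permutation p = 0.00638, adjusted p = 0.017, rho = 0.52, permutation p = 0.0051) and 0.47 without the 2 farthest arrays. Within image run 1 that relation passed by rho (0.47, adjusted p = 0.0468) and not by r (0.44, adjusted p = 0.0869), and on deviations from the group means by neither (r = 0.26, adjusted p = 0.261, rho = 0.32, adjusted p = 0.174). Over all arrays the remaining 5 did not pass: B cell with T cell genes (r = 0.23, rho = 0.27), with proliferation genes (r = 0.15, rho = 0.14) and with parietal cell genes (r = -0.03, rho = -0.06), and parietal cell with chief cell genes (r = 0.34, rho = 0.31) and with acinar genes (r = 0.08, rho = 0.06). Their permutation p for r was 0.229, 0.437, 0.884, 0.0749 and 0.682, and for rho 0.164, 0.452, 0.762, 0.105 and 0.765. B cell and T cell genes passed within image run 1 by rho (0.48, adjusted p = 0.0446) and not by r (0.40, adjusted p = 0.102).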

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

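The tests of pancreatic RNA, chief cells, image runs (image run 3 in the splits too) and single arrays, and of B lineage cells in series A, were chosen only after the result was seen, while those of abundant transcripts, of spread and of other splits of the samples were written before it.

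Pancreatic acinar genes lay below the pool, with a median of -1.62. Fewer chief cells in the biopsies, and the image run, are argued against: 4 chief cell genes that the pancreas lacks had a median of -0.14 (Pgc -0.52 ± 0.18, Lipf -0.28 ± 0.14, Cblif 0.02 ± 0.09 and Chia1 -0.0040 ± 0.15, SE), and the acinar median within image run 1 was -1.67. Pancreatic RNA in the control pool is a candidate explanation, as the chief cell genes lay above the acinar genes by 1.476. That value comes from the same medians as the argument against fewer chief cells and is no separate support. Any other cause that spares these 4 genes would give it too. With the ratio turned, the same values would mean pancreatic RNA in the biopsies, which stays open too. In either direction the mean of the acinar list varied between arrays from -2.85 to 0.86. The pool, taken as the same on every array, cannot give that variation by itself. Differing amounts of pancreatic RNA in the biopsies were not tested as its cause. Of 22 acinar genes Clps (0.0090), Prss2 (0.27), Amy2a5 (0.04) and Cuzd1 (0.13) were not lower. For these genes that goes against pancreatic RNA in the pool and stays open, as do faults of single probes and the authors' normalization.

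Ribosomal protein genes were higher in series D than in the mean of the other series, with a median difference of 0.46. With an estimated correlation the list did not pass (adjusted p = 0.627). The image run stays open: the median was 0.37 within image run 1, where the list passed with the preset correlation (adjusted p = 4.99e-09) and not with an estimated one (adjusted p = 0.908), and its mean per array differed there by 0.34 ± 0.15 (SE between arrays), while the arrays of series B and D in image run 3 had medians of 0.98 and 1.22. A dye or intensity bias shared by abundant transcripts is a candidate cause, since 22 other abundant transcripts had a median difference of 0.29 ± 0.06 (bootstrap SE). A wider spread of all ratios on series D arrays stays open, since after scaling all arrays to 1 spread the median difference was 0.19, between the bounds set for and against it, and no biological difference was tested.

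Jchain was lower in series A than in the mean of the other series by -3.56 ± 0.43 (SE, adjusted p = 4.04e-05) and Igha by -1.69 ± 0.31. The image run and single arrays are argued against as the whole cause, as Jchain differed by -3.54 within image run 1 (adjusted p = 8.92e-05) and by -3.39 at the least with 1 array left out. Image order within that run is not excluded, as all image numbers of series A lie below those of series C and D. Series B replicates 1 and 3 lie among those of series A, with Jchain at 2.34 and 2.46. Fewer B lineage cells in the series A biopsies may explain it, since the B cell list was lower there (median -0.45, adjusted p = 0.00243), but not with an estimated correlation (adjusted p = 0.0652), nor against series D alone (-0.32, adjusted p = 0.158), where Jchain differed most, and the MHC class I list moved further (-0.73). The plasma cell list had a median difference of -0.02 (adjusted p = 0.292). The authors' normalization, mislabelled samples and what the letter A stands for remain untested.

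Differences between series drew attention with 39 genes in the F test, 2 between series A and B, 209 between series A and D, 2 between series B and D and 36 between series C and D. Each was set against 100 splits of the same samples, the real one included. By this test chance was unlikely for the F test (39 genes, highest other split 0, 1 of 100 as large), series A against B (2, highest other 1, 1 of 100) and series A against D (209, highest other 1, 1 of 100). It was not excluded: 100 splits can show no share below 1 of 100, and the comparisons were not adjusted for their number. The splits also take the biopsies as independent, which the labels do not show. They exchange arrays without regard to image number, while within image run 1 the numbers of series A and B all lie below those of series C and D. A drift with image order could thus not be told apart from a difference of series A or B from series C or D. For series C against D (36, highest other 47, 2 of 100) chance was unlikely only where image runs are left out of account. The split with 47 genes put both series D arrays of image run 3 in 1 group, as the real one does. The real comparison gave 66 genes within image run 1 and 18 with the image run as a block. For series B against D chance stayed open (2 genes, highest other 3, 5 of 100). Series A against C and B against C gave 0 genes in limma (399 and 626 at an unadjusted p under 0.05), so that 100 of 100 splits were as large by construction and nothing follows about chance (highest other 1 and 32). The split of series B and C with 32 genes also put both series B arrays of image run 3 in 1 group. Splits with the arrays of image run 3 in 1 group gave any gene in 12 of 50 cases for series C and D, 1 of them as many as the real split, and splits with them apart in 2 of 49, which may come from a structure of the samples in that pair. Little or no such excess was seen for series A and D (3 of 46 and 2 of 53), A and B (0 of 52 and 2 of 47) or B and D (0 of 3 and 7 of 96). For series B and C the values were 2 of 58 and 0 of 41, too few to tell such a structure.

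A sample far from the others of its series, by the gap to its nearest neighbour over the range of the series, was found in 34 of 336 tests (10.12%), and in 0 on arrays of image run 3. Those arrays come in pairs within series B and D. As each can hide the other from this rule, the 0 says little about them. Chance alone would give about 1 in 20 such groups. On series C replicate 7 Amy1 was 0.26, Try4 -0.45, Try5 0.20, the acinar list 0.026, the mast cell list -1.29 and the fibroblast and matrix list -0.50. On series A replicate 6 Vav3 was -1.12, Nfkb2 -1.16, Adam9 -1.06, Cd164 -1.11, the fibroblast and matrix list -0.48, the oxidative phosphorylation list -0.55 and the ribosomal list -0.59. On series C replicate 2 Oplah was -2.54, Lhb 4.14, 1810021M19Rik 1.36 and Lrwd1 1.64. On series A replicate 11 Tgfb1 was 0.028, Man1b1 -3.17 and the chief cell list 0.61, and on series A replicate 10 Cldn13 was 5.27 and Lhb -0.41. On series D replicate 2 Amy1 was -10.28, the plasma cell list 0.59 and the interferon list 0.60. Single values were Mmd on series D replicate 5 (-1.59), Fgd6 on series B replicate 5 (-1.68), Lyzl1 on series C replicate 4 (3.11), Adam9 on series D replicate 1 (2.95) and Plac8 on series A replicate 9 (0.74). For lists they were lymphoid follicle on series D replicate 3 (-0.33), interferon on series C replicate 1 (0.53), endothelium on series A replicate 8 (-0.78) and red cell on series B replicate 3 (1.02).

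Probes with no gene symbol or several also carried signal: of 20040 such probes tested, 4417 passed against the pool, 2080 higher and 2337 lower, and 109 passed the F test.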

How the results depend on the processing

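Leaving out the 5 arrays of widest spread, the gene lists within image run 1, and image run 3 alone, were chosen after seeing the data, and the other alternatives before the data were examined. For the settings given here the cause was not tested unless their construction shows it.

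The robust prior and the filter of at least 2 arrays per group kept every count within 1.5 times. The values with no centring did so except for series C against D (18 genes), and genes measured on all 29 arrays except for series B against D (22) and the F test (67). Under quantile normalization 4086 genes passed against the pool, 600 in series A, 1006 in series B, 474 in series C and 4 for series C against D. With all arrays scaled to 1 spread the counts were 190 in series A, 494 in series B, 216 in series C and 329 in series D. For pairs they were 0 for series A against B, 41 for A against D, 0 for B against D and 2 for C against D, and the F test gave 3. With array weights series A gave 210, B 594 and C 135, the pairs A and B 43, A and C 12, A and D 552, B and C 2 and B and D 90, and the F test 211.

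With each probe by itself, which tests more items, 8914 probes passed against the pool, 764 in series B, 272 in series C, 6281 in series D, 19 for series A against B, 756 for A against D, 30 for B against D, 80 for C against D and 193 for the F test. With the arrays of the groups compared alone, which are fewer, limma gave 100 genes in series B, 0 in series C, 255 in series D, 62 for series A against D, and 0 for B against D and C against D. These 3 comparisons with 0 had 1384, 1228 and 1544 genes at an unadjusted p under 0.05 in the fit on all arrays.

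With the image run as a block 160 genes passed in series C, 1 for series A against B, 58 for A against D, 5 for B against D, 18 for C against D and 20 in the F test. Series A and C lie in image run 1 alone. Against the pool the block moved their values by a run effect estimated from series B and D. Within image run 1, which holds fewer arrays, the counts were 1224 against the pool, 39 in series B and 875 in series D. They were 1 for series A against B, 53 for B against D, 66 for C against D and 65 for the F test. Image run 3 alone, with 2 arrays of each series, gave 0 genes in series B, 0 in series D and 0 for B against D in limma (1629, 2327 and 470 at an unadjusted p under 0.05), where 2 residual degrees of freedom leave little chance of a call. Without the 5 arrays of widest spread 1530 genes passed against the pool, 588 in series D, 1 for series A against B, 33 for A against D, 66 for B against D and 65 for C against D.

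The share of calls that were higher moved by over 10 points with the scaling. Against the pool it was 35.6%, and 13% with no centring and 10.4% with quantile normalization. For series B it was 36.8%, 17.5% and 11.7%, for series C 22.7%, 8.9% and 5.3%, and for series D 38.1%, 13.3% and 15.6%. For series A against D it was 53.6%, and 68.2% with no centring. For series C against D it was 36.1%, 61.1% with no centring, 75% with quantile normalization and 50% after scaling to 1 spread. With no centring the median of all genes in series D against the pool moved from -0.11 to -0.27. Against the pool 1910 of the 2346 genes passed with no centring and 1932 with quantile normalization.

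With 1 array left out the counts ran from 1841 to 2654 against the pool, 0 to 1 in series A, 94 to 243 in series B, 34 to 77 in series C and 991 to 2114 in series D. For pairs they ran from 2 to 3 for series A against B, 29 to 416 for A against D, 0 to 49 for B against D and 3 to 106 for C against D, and from 24 to 158 for the F test. For series A against C and B against C they stayed at 0 in limma (399 and 626 genes at an unadjusted p under 0.05). Series D replicate 5 gave the highest count in 6 of these comparisons.

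The labels do not say whether a shared replicate number pairs samples. Deviations of samples with the same number correlated with a median r of 0.06 over 30 pairs (-0.18 to 0.26, with 8 over 0.1). For 284 pairs of different numbers the median was -0.01, with 46 over 0.1. Correlations this weak do not decide whether the samples were paired. With the replicate block series A against B gave 5 genes, A against C 10 (among them Fgd6, -3.95, adjusted p = 0.00337), A against D 327, B against C 0, B against D 0, C against D 0 and the F test 31 (without Plac8, Nt5e, Adam9, Rbm3, Cd164 and Lrwd1), and the gene lists gave 47 calls between series, among them 33 of the 45 made without it.

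Of 82 calls of gene lists, 28 held with a correlation estimated from residuals, 82 with no centring, 65 with the image run as a block, 64 within image run 1 and 60 without the widest arrays, and with new calls included these settings gave 28, 87, 75, 74 and 73. The direction of all 82 held with no centring, with quantile normalization and after scaling, where 82, 72 and 62 were called. Within image run 1 the direction of the test turned against the pool for the general epithelium (median -0.10), smooth muscle (-0.057), forestomach (-0.12) and endoplasmic reticulum stress (-0.05) lists, and for oxidative phosphorylation in series B (-0.074) and in series A against B (0.039). Without the widest arrays it turned for the general epithelium (-0.082) and smooth muscle (0.011) lists and for oxidative phosphorylation in series A against B (0.04), and with no centring for proliferation (-0.14) and skeletal muscle (-0.17). Of 8 relations between lists 3 passed by r and by rho, 3 and 3 without the 2 farthest arrays, 2 and 4 within image run 1, and 2 and 2 on deviations from the group means.

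No named gene turned its direction. Calls of named genes that were lost numbered 5 with no centring, 9 with quantile normalization, 34 with all arrays scaled to 1 spread, 5 with array weights, 8 within image run 1, 9 with the image run as a block, 21 with the groups compared alone, 18 with the replicate block and 14 without the widest arrays, and 114 of all named genes times arrays left out. Signal over background, which limits ratios of weak spots, was not analysed here.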

Other observations

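Within lists that did not pass against the pool, single genes went both ways (adjusted p from limma). Col1a2 (0.43 ± 0.08, SE, adjusted p = 0.000485) and Col1a1 (0.39, adjusted p = 0.00318), chains of type I collagen, were higher than the pool, while Col6a2 (-0.84, adjusted p = 0.00374) and Fbln2 (-0.55, adjusted p = 0.00482) were lower. Of the mast cell list Kit (-0.65, adjusted p = 0.000933) was lower and the protease Mcpt4 (0.31, adjusted p = 0.0214) higher. The gastric hormone gene Gast (-0.92, adjusted p = 4.54e-05) and the histamine-forming enzyme Hdc (-0.83, adjusted p = 0.00187) were lower, and Chga (0.39, adjusted p = 0.017) was higher. Of the proliferation list Aurkb (-0.48, adjusted p = 0.00217), Rrm1 (-0.32) and Racgap1 (-0.44) were lower and Fen1 (0.35) higher. The plasma cell list held Jchain, which was higher, and Ell2 (-0.43, adjusted p = 0.00504) and Txndc5 (-0.34, adjusted p = 0.0276), which were lower. Kcnmb1 (-1.12, adjusted p = 0.000599) and Slc4a1 (-0.77, adjusted p = 0.00956) were lower than the pool.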
